A study of Drosophila melanogaster with 2 samples.

How the data were processed

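Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed for the cohesin subunit Stromalin (SA) in Kc167 cells, a Drosophila melanogaster line of embryonic origin with blood-cell character. One library came from wild-type (WT) cells and 1 from cells depleted of the kinase Haspin by RNA interference (Haspin KD). Per the labels' protocols, depletion lasted 7 days, with 10 µg/ml of double-stranded RNA given every 48 h. Whether the WT cells received a control double-stranded RNA is not given in the sources used here. Chromatin was fixed with 1% formaldehyde for 10 min and sheared to fragments of 200 to 500 bp, per the labels' protocols.

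Bowtie 0.12.9, MACS 1.4.2 and the genome build dm3 are named in the submitters' processing notes. The files are peak lists of the authors, 1 for each library and none pooled. Each line gives a chromosome, a start, an end, a running peak name and a score. The score that the authors deposited lies on the scale on which MACS 1.4 writes the negative log10 of a p-value multiplied by 10, and it depends on the depth of the library. The other deposited columns used were the start and end positions in bp, and the arm names (such as 3RHet, U and Uextra) are those of Release 5, which is dm3. The deposited names of both lists refer to the same second sequencing run, taken here as a common control. Alignment options, peak-calling options, read numbers and the depth of each library are not given in the sources used here. Peak numbers, widths and scores all depend on depth, so a difference between the lists can come from depth as well as from SA. A common control can also place peaks at the same positions in both lists.

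Starts were converted to positions counted from 1. The names were numbered without gaps in both lists. A peak counted as shared when a peak of the other list overlapped it by at least 1 bp. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The overlap function was tested on simulated data, where it found 400 of 400 sites carrying a second peak and called 0 of the others shared. On the deposited lists it gave 687 overlapped WT peaks, and bedtools 2.31.1 gave 687. Shares carry exact Clopper-Pearson 95% confidence intervals and numbers of peaks carry exact Poisson 95% intervals (scipy 1.17.1). Both cover counting error only, and neighbouring peaks are not independent. The chance level of overlap was taken from 1000 random placements of the Haspin KD peaks of the arms X, 2L, 2R, 3L, 3R and 4. Each peak was placed on its own arm, between the first and the last peak of either list. Scores were used to rank peaks within their own list and to divide each list into 5 classes of nearly equal size. They were also used to filter both lists at the same limit of 100, which need not mean the same enrichment in libraries of different depth. Pairs were formed where 1 WT peak and 1 Haspin KD peak overlapped each other and no other peak. Paired peaks were ranked by score within each list among the paired peaks alone, so that both rankings had the same length. Figures were drawn with matplotlib 3.10.9.

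There was 1 library per group. No test between the conditions was therefore made, no difference has a replicate check, and each comparison describes these 2 libraries. The peaks named in the text were fixed by rule before the data were examined. They are the 10 highest-scoring peaks of each list and the 5 highest-scoring peaks of each list without an overlapping peak in the other. The 3 widest peaks of each list, the 3 regions of 3R, windows of 1 Mb and the division of Uextra at 1 Mb were chosen after their values were seen. The alternatives were stricter and looser definitions of overlap, a score of at least 100, lists of equal length, peaks of fixed width, merged neighbouring peaks and the 6 arms alone. The placement of peaks at promoters and in 11 lists of genes had also been planned. Both need gene coordinates in dm3. The gene table used here is on Release 6, coordinates were not converted between builds, and peaks are given by position only. The position of these peaks relative to genes was therefore not analysed here.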

Results

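The series asked where Stromalin (SA), a subunit of the cohesin ring that holds sister chromatids together and shapes chromatin loops, lies along the genome in Kc167 cells with and without the kinase Haspin. The data were 2 lists of SA peaks on build dm3, 1 from WT cells and 1 from Haspin KD cells. With 1 library per condition, the differences below have no replicate error and describe the libraries. Intervals are 95% intervals for counting error. The depletion of Haspin itself cannot be read from peak positions.

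The WT library held 1551 SA peaks and the Haspin KD library held 894, which is 57.6% of the WT number. The exact Poisson intervals were 1475 to 1630 for WT and 836 to 955 for Haspin KD. WT peaks covered 3.79 Mb and Haspin KD peaks covered 1.87 Mb, or 49.3% of the WT length. The median peak was 1657 bp wide in WT (quartiles 1162 and 2648 bp) and 1451 bp wide in Haspin KD (quartiles 1067 and 2366 bp). Broad regions were present in both lists, with 27 WT peaks and 13 Haspin KD peaks over 10 kb. The widest WT peak lay on X from 12609670 to 12648670 and spanned 39.0 kb, and 6 Haspin KD peaks overlapped it. On 3L, the WT peak from 3422516 to 3453443 spanned 30.9 kb and was overlapped by 8 Haspin KD peaks. The widest Haspin KD peak, on 3L from 8667920 to 8691352, spanned 23.4 kb and lay within a WT peak of 27.0 kb from 8667573 to 8694576. Scores began at 50.06 in WT and at 50.01 in Haspin KD, and depth is unknown for both libraries.

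SA peaks were fewer in Haspin KD on each of the 6 main arms. 3L, with the most peaks in both libraries, held 339 WT peaks (304 to 377) and 208 Haspin KD peaks (181 to 238). 3R held 314 WT peaks (280 to 351) and 177 Haspin KD peaks (152 to 205). On X there were 263 WT peaks (232 to 297) and 162 Haspin KD peaks (138 to 189). 2L held 265 and 140, and 2R held 232 and 112. For these 5 arms the intervals of the libraries did not overlap. The short arm 4 held 17 WT peaks (9.90 to 27.2) and 8 Haspin KD peaks (3.45 to 15.8), whose intervals overlapped. The number of Haspin KD peaks per WT peak was 0.616 on X, 0.614 on 3L, 0.564 on 3R, 0.528 on 2L, 0.483 on 2R and 0.471 on 4. Over the stretch between the first and last peak of an arm, WT peaks numbered from 11.2 per Mb on 2R to 15.4 per Mb on 4. Haspin KD peaks numbered from 5.40 per Mb on 2R to 8.52 per Mb on 3L.

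**Figure D1:**
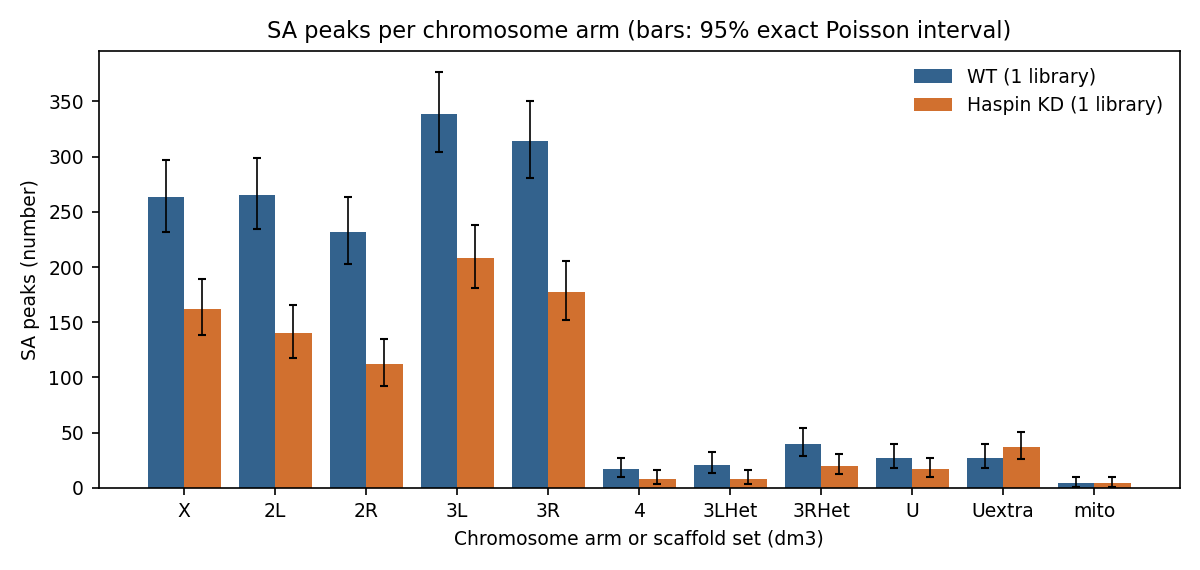
Number of SA peaks (vertical axis) on each chromosome arm or set of scaffolds of dm3 (horizontal axis) in the WT library and the Haspin KD library, with exact Poisson 95% intervals as error bars; 2LHet and 2RHet, with at most 1 peak each, are not drawn. The WT library held more peaks on all 6 arms (339 against 208 on 3L), and Uextra held 27 WT peaks and 37 Haspin KD peaks.

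Heterochromatic scaffolds, assembled separately from the arms, held 63 WT peaks (48.4 to 80.6) and 29 Haspin KD peaks (19.4 to 41.6). Most were on 3RHet, with 40 in WT and 20 in Haspin KD, and on 3LHet, with 21 and 8. U, which joins scaffolds not placed on an arm, held 27 WT and 17 Haspin KD peaks. Uextra, which joins further small unplaced scaffolds, held 27 WT peaks (17.8 to 39.3) and 37 Haspin KD peaks (26.1 to 51.0), with overlapping intervals. The mitochondrial genome carried 4 peaks in each list, which formed 4 overlapping pairs. In 3 of these pairs both ends lay within 20 bp of each other.

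Most SA sites of the Haspin KD library were also SA sites of the WT library, while less than 50% of the WT sites were called in Haspin KD. Of the 894 Haspin KD peaks, 828 overlapped a WT peak, a share of 92.6% (exact interval 90.7% to 94.2%). Of the 1551 WT peaks, 687 overlapped a Haspin KD peak, a share of 44.3% (41.8% to 46.8%). The lists had 1.70 Mb in common, which is 91.1% of the Haspin KD length and 44.9% of the WT length. On the 6 arms, 773 of 807 Haspin KD peaks overlapped a WT peak, against a mean of 40.9 and a highest value of 61 in 1000 random placements. From the WT side, 634 of 1430 peaks were overlapped, against a mean of 45.1 and a highest value of 70. The random placements do not model the control run that both lists appear to share. With the WT list limited to its 894 highest-scoring peaks, the shares were 65.4% of WT peaks and 82.3% of Haspin KD peaks. Requiring the overlap to cover 50% of each peak gave 31.7% and 54.9%.

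The strongest SA sites were found in both libraries. All 10 of the highest-scoring WT peaks overlapped a Haspin KD peak, and 5 of them overlapped 2 or more. Of these 10 sites, 4 were also overlapped by one of the 10 highest Haspin KD peaks. They were on 3L from 7853442 to 7861686, on X from 8784285 to 8792910, on 3R from 4632481 to 4643393 and on 3L from 3413274 to 3422435. The first 2 of these had the top WT score of 3100, which 5 WT peaks reached. The highest Haspin KD score was 3100 as well, so this value may be a ceiling and does not order the peaks that reached it. The other peaks at that score were on 2L from 19154223 to 19167165, on 3L from 11339301 to 11349030 and on X from 3333252 to 3342184. The remaining 3 of the 10 lay on 2R from 7082508 to 7096685 with a score of 3014.93, on 2L from 158717 to 169180 with 2638.43, and on X from 9474975 to 9481168 with 2585.70. The Haspin KD peak overlapping the 2L site from 19154223 ranked only 100 in its list, and that overlapping the 2R site ranked 247. At the other sites the highest overlapping Haspin KD peak ranked from 2 to 25. These are the authors' scores, and scores and ranks hold within their own list.

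All 10 of the highest-scoring Haspin KD peaks overlapped a WT peak. The highest and the fourth were mitochondrial, from 14784 to 15940 with a score of 3100 and from 16936 to 17872 with a score of 1963.73. The WT peaks that they overlapped ranked 46 and 180 in the WT list. Whether the mitochondrial peaks mark SA binding was not tested here. The nuclear peak with the highest score, 2306.23, lay on 3L from 7854827 to 7861680. It was followed by peaks on 2R from 2037816 to 2039409, on 3L from 3415838 to 3422275, on 3R from 4634192 to 4643435 and on X from 8785275 to 8792580. The others were on 3L from 3431180 to 3441917, on X from 12642965 to 12648669 and on X from 18528153 to 18530334.

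WT sites without a Haspin KD peak were mostly sites of low WT score. Each list was divided by score into 5 classes of nearly equal size. In the lowest class of the WT list, with scores of 50.06 to 72.75, 42 of 310 peaks were shared, or 13.5% (9.94% to 17.9%). The share was 17.4% (13.4% to 22.1%) in the next class, 31.9% (26.8% to 37.4%) in the middle class and 63.9% (58.2% to 69.2%) in the fourth. In the highest class, with scores of at least 444.18, 294 of 311 peaks were shared, or 94.5% (91.4% to 96.8%). Shared WT peaks had a median width of 2479 bp and WT peaks without a Haspin KD peak had a median width of 1337 bp. In the Haspin KD list the share with a WT peak was 79.8% (73.1% to 85.4%) in the lowest class and 97.2% (93.6% to 99.1%) in the highest.

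**Figure D2:**
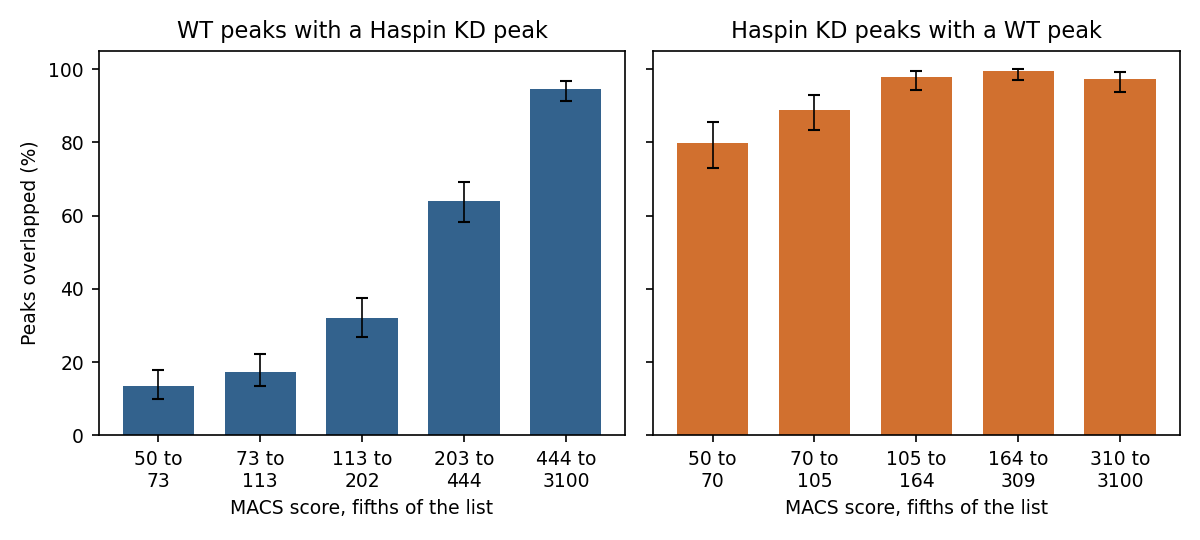
Percentage of peaks overlapped by a peak of the other list (vertical axis) in each of the 5 score classes of the WT list (left) and of the Haspin KD list (right), by the MACS score within that list (horizontal axis); error bars are exact 95% intervals. The WT share goes from 13.5% in the lowest to 94.5% in the highest class, and the Haspin KD share from 79.8% to 97.2%.

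The share of WT peaks found in Haspin KD was compared between the arms. It was 49.0% (43.5% to 54.4%) on 3L, 47.5% (41.4% to 53.8%) on X, 42.6% (36.6% to 48.8%) on 2L, 42.0% (36.5% to 47.7%) on 3R and 40.1% (33.7% to 46.7%) on 2R. Arm 4 had 5 of 17, or 29.4% (10.3% to 56.0%). The heterochromatic scaffolds had 21 of 63, or 33.3% (22.0% to 46.3%). With the WT list limited to its 894 highest-scoring peaks, arm 4 had 50%, from 4 of 8 peaks. No test of the difference between arms was made.

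Among 532 pairs of single overlapping peaks, the Haspin KD peak was the narrower one in 473, or 88.9%. On the arms this held for 444 of 483 pairs, with median widths of 2199 bp in WT and 1391 bp in Haspin KD. On U it held for 3 of 10 pairs and on Uextra past its first Mb for 3 of 9, where the median widths were 569 bp in WT and 565 bp in Haspin KD. Called width depends on depth as well as on the extent of binding.

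A few strong WT sites lacked a Haspin KD peak. In the highest score class there were 17 such sites. By far the highest score among them, 2120.33 (the WT list's rank 20), belonged to a peak on 3R from 19135412 to 19144034, and the nearest Haspin KD peak was 13.0 kb away. The next were on 3L from 21000202 to 21005671 with a score of 739.80, on 3R from 8841353 to 8845472 with 612.67, on 3R from 17437424 to 17441096 with 608.18 and on 2L from 11037126 to 11041332 with 573.13. The nearest Haspin KD peaks were 508, 2127, 2404 and 2993 bp away.

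Of the 66 Haspin KD peaks without a WT peak, 34 were on the arms, and 15 of those were on 3R. The other 32 were outside the arms, and 20 of those were on Uextra. In the highest score class of the Haspin KD list 5 peaks had no WT peak, and all 5 were on 3R. The highest of them lay from 12045084 to 12052707 with a score of 952.52, and another lay from 12073538 to 12078386 with 751.30. Between these a peak of 19132 bp, from 12052844 to 12071975, had a score of 54.25. Together they filled a stretch between WT peaks that ended at 12044588 and began at 12079101. The gaps to the nearest WT peak were 495 bp for the first and 714 bp for the second. A separate group lay from 3930712 to 3948287, with scores of 450.62, 102.57 and 746.48, and the nearest WT peak was 232 kb from its end. The last, from 19160173 to 19163512 with a score of 382.49, was 3.66 kb from a WT peak. It lay on the far side of a gap from the strong WT peak that ended at 19144034.

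**Figure D3:**
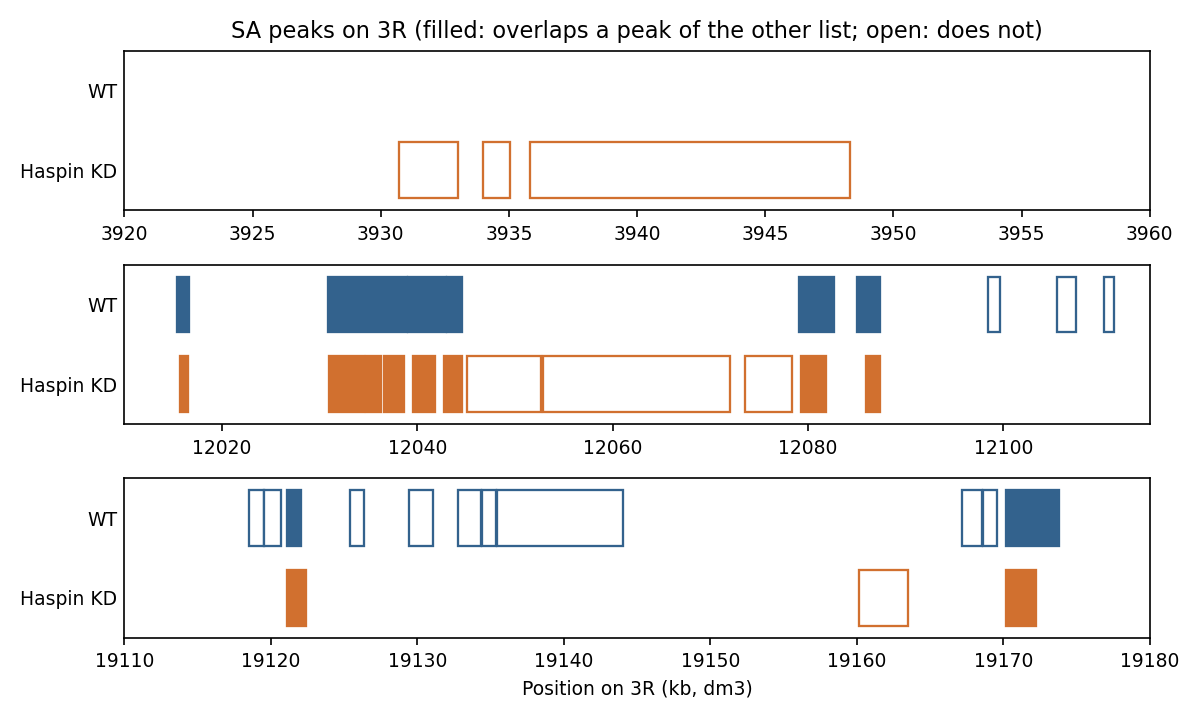
Position on 3R in kb of dm3 (horizontal axis) of the SA peaks of each library (rows) in 3 regions; filled boxes overlap a peak of the other list and open boxes do not. Haspin KD peaks without a WT peak lie from 3930712 to 3948287 (top) and from 12045084 to 12078386 (middle), and the WT peak from 19135412 to 19144034 has no Haspin KD peak (bottom).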

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

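The alternatives were fixed before the data were examined. The Haspin KD list stayed the shorter one wherever the lists were not set to equal length. Under each definition of overlap and each filter its share of peaks found in the other list stayed above that of the WT list. List length contributes to this. Under 50% of each peak the same number, 491, was shared from both sides, of 1551 WT and of 894 Haspin KD peaks. Of 40 alternatives, 20 stayed within the interval of the reported value (within 1.5 times for numbers of peaks) and 20 did not. The share of WT peaks with a Haspin KD peak, 44.3%, became 31.7% when the overlap had to cover 50% of each peak and 39.0% with 500 bp to each side of the midpoint. It became 47.3% with peaks less than 1000 bp apart merged, 50.2% with a gap of up to 1000 bp allowed, 60.8% for WT peaks with a score of at least 100, and 65.4% for the 894 highest-scoring WT peaks. The share of Haspin KD peaks with a WT peak, 92.6%, became 54.9% under 50% of each peak, 68.9% with 500 bp to each side of the midpoint, 82.3% with the shortened WT list, 95.8% on the 6 arms alone and 97.3% for Haspin KD peaks with a score of at least 100. A score of at least 100 left 997 WT and 548 Haspin KD peaks, a proportion of 55.0% against 57.6% for all peaks. The shared part of the lowest WT score class became 21.0% with a gap of up to 1000 bp, and that of the highest became 75.6% with 500 bp to each side of the midpoint. With the shortened WT list the shared part was 70.5% on X, 66.0% on 2L, 61.2% on 2R, 69.2% on 3L, 59.0% on 3R and 50% (4 of 8, against 5 of 17) on 4. A stricter overlap can only lower the shares, and limiting the WT list removes low-scoring peaks. An overlap of 50% of the smaller peak changed the shares little, to 43.3% of WT and 91.2% of Haspin KD peaks. A peak that passes 50% of the smaller peak but fails 50% of each peak must differ in width from its partner. The further drops to 31.7% and 54.9% therefore came from unequal widths of overlapping peaks. The Haspin KD peaks were narrower and sometimes split. Whether this gave the drops with 500 bp to each side of the midpoint was not tested. Promoters and gene lists were not run, because gene coordinates in dm3 were not used here. No paired analysis was possible because each group has 1 library. Depth is unknown, so no result separates a site that lost SA from a site that fell below the limit of the peak caller.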

Other observations

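The tests in this part were all chosen after the results were seen. Across 121 windows of 1 Mb on the 6 arms, 111 held fewer Haspin KD than WT peaks, 7 held equal numbers and 3 held more. Those 3 were on X from 12 to 13 Mb with 9 WT and 15 Haspin KD peaks, on 3R from 17 to 18 Mb with 24 and 28, and on 3R from 3 to 4 Mb with 1 and 3. On X, the WT peaks of that window covered 80.8 kb and the Haspin KD peaks 71.3 kb, and 6 Haspin KD peaks overlapped 1 wide WT peak there. The covered lengths were 83.3 and 57.1 kb on 3R from 17 to 18 Mb, and 0.945 and 15.8 kb from 3 to 4 Mb. On 3R from 12 to 13 Mb, Haspin KD had fewer peaks (12 against 17) but a larger covered length (48.9 against 36.3 kb). The window with the most WT peaks was on 3R from 19 to 20 Mb, with 32 WT and 11 Haspin KD peaks. None of the 100 windows with at least 5 WT peaks was without a Haspin KD peak. On the arms, 43.8% of the 796 WT peaks without a Haspin KD peak lay within 10 kb of one. The mean was 14.8% and the highest value 20.6% in 1000 random placements. These placements spread the Haspin KD peaks evenly along each arm, whereas 773 of the 807 overlapped a WT peak. The excess therefore cannot set WT peaks without a Haspin KD peak apart from WT peaks in general.

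The smaller number of Haspin KD peaks on the arms is the main difference between the lists, at 0.564 Haspin KD peaks per WT peak. One hypothesis is that lower depth or weaker enrichment removed the lowest-scoring sites. The scores go with it: 94.5% of the highest WT score class was shared against 13.5% of the lowest. Width differed as well, with medians of 4273 bp in the highest and 1032.5 bp in the lowest class, and wide peaks overlap more easily. With 500 bp to each side of the midpoint the shares were 75.6% and 10.6%. In the lowest 2 WT score classes, the shared part was 12.5% on the arms (9.78% to 15.6%), 21.3% on the heterochromatic scaffolds (10.7% to 35.7%), 30.0% on U (11.9% to 54.3%) and 56.5% on Uextra (34.5% to 76.8%), and only the Uextra interval lay apart from that of the arms. The other hypothesis is that less SA was bound across its sites after Haspin depletion, which would give the same order of loss. These cannot be told apart here, because each condition has 1 library and neither depth nor signal outside peaks was used.

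Part of Uextra differed from the arms in direction. Past its first Mb, Uextra held 28 Haspin KD peaks (exact Poisson interval 18.6 to 40.5) and 9 WT peaks (4.12 to 17.1), whereas its first Mb held 9 Haspin KD and 18 WT peaks and U held 17 and 27. The peaks past the first Mb were narrow, with medians of 501 bp in Haspin KD and 569 bp in WT, and in 7 of 9 pairs both ends lay within 20 bp of each other. If a lower sequencing depth of the Haspin KD library removed equally low-scoring sites alike, similar shares would remain on Uextra and the arms. Of the low-scoring WT peaks, 13 of 23 on Uextra were shared (56.5%), against 66 of 529 on the arms. That share rests on the stretch past the first Mb, with 8 of 8. The first Mb had 5 of 15 (11.8% to 61.6%), whose interval overlapped that of the arms. The stretch was set apart after its larger number of Haspin KD peaks was seen, so this share cannot decide on depth. Uextra as a whole held 37 Haspin KD peaks (26.1 to 51.0) and 27 WT peaks (17.8 to 39.3), with overlapping intervals. Another candidate explanation, more DNA other than SA-bound nuclear chromatin in the Haspin KD library, stays open: of the mitochondrial, U and first-Mb Uextra pairs, 14 of 20 or 70.0% (45.7% to 88.1%) ranked higher in the Haspin KD list, against 48.2% of the 483 arm pairs. By class these were 4 of 4 mitochondrial, 9 of 10 U and 1 of 6 first-Mb Uextra pairs. Beside them were 14 of 20 on the heterochromatic scaffolds and 9 of 9 on Uextra past its first Mb. On the latter the median rank was 502 in WT and 215 in Haspin KD. The classes were not matched on WT rank. Its median was 246 for the arm pairs, 268.5 for mitochondrial, 457 for U, 489 for first-Mb Uextra and 446.5 for heterochromatic pairs. In Haspin KD the medians were 267, 74, 193, 500.5 and 391, in the same order. Pairs ranked low in WT have more room to rise, yet first-Mb Uextra and heterochromatic pairs moved little beside U pairs. A low WT rank alone therefore did not go with a large rise. The classes outside the arms hold few pairs and did not all move the same way, so this comparison cannot decide. A low coverage of these sequences in the common control, and a biological origin, were not tested.

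The strong Haspin KD peaks on 3R without a WT peak stand apart from the loss of weak sites. Whether they were sites just below the WT cut-off was not tested, because signal outside peaks was not used here. A wide WT region tested as a whole and scored below the cut-off is a possible explanation for the stretch between 12044588 and 12079101. Of the 40 peaks over 10 kb in both lists, 7.50% scored under 100 (1.57% to 20.4%). One of these 3 was the Haspin KD peak of 19132 bp inside that stretch. Wide regions that scored below the cut-off are in neither list, so this share cannot decide and the explanation stays open. A gain of SA binding after Haspin depletion at 3R from 3930712 to 3948287, 232 kb from the nearest WT peak, is a hypothesis that read coverage or a second library would test.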
